A study of Mus musculus with 6 samples.

How the data were processed

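RNA was measured in 6 libraries from bone marrow cells of wild-type C57BL/6J mice, a laboratory inbred strain, kept for 3 days in medium with FLT3LG at 50 ng/ml. Per the labels, 3 libraries had no further addition (control, replicates 1, 2 and 4) and 3 received recombinant human midkine at 10 ng/ml (replicates 3, 4 and 5). The labels call each condition a triplicate and do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. Libraries were made with the QuantSeq 3′ kit (FWD), per the labels' protocols. It primes on poly(A) and yields 1 fragment per transcript near the 3′ end, so values are not scaled to gene length. RNA integrity is given in the labels only as an average and a range over samples, not per library.

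The deposited values are normalized counts per gene symbol, a signal that is never negative. The submitters' processing notes name FastQC 0.11.0, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, HTSeq and DESeq2, and the build GRCm38 (mm10). The annotation release, the strand setting of the counting, the treatment of reads that map to several places and the gene filter are not given in the sources used here. Reads of overlapping genes on opposite strands and of near-identical genes can therefore not be told apart.

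Every value was a whole multiple of 1 step per library, as for gene counts divided by a size factor by the authors. Dividing by that step gave whole reads for 100% of values in each library, within a tolerance of 0.01 reads. The size factors recovered in this way ranged from 0.947 to 1.10. Recovered reads per library ranged from 5985684 to 7233960. A floor of 3 reads corresponded to at most 5.01e-05% of a library. The lowest sum of reads of any gene over the 6 libraries was 3. Wilson 95% intervals and floors cover counting error only, since reads were not counted by molecular identifiers here. The table held 0 other columns of per-sample values.

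The table held 15443 gene symbols. Of these, 15353 matched a single gene of GENCODE M21 on GRCm38, 30 matched several and 60 matched none. Coordinates, gene classes and exon overlaps were taken from that annotation, and the GC content of the last 300 nt from its longest transcript per gene.

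The main test was limma 3.58.1 (lmFit and eBayes with trend, in R 4.3.3) on log2(normalized count + 1). Genes with a mean under 5 over the 6 libraries were left out, which left 13543 genes. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, midkine minus control, which understates the change of low genes. Group values are means ± SD of the normalized counts over 3 libraries.

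Fixed before the data were examined were the tests, most of the other settings tried, the rule for named genes and 30 gene lists. The lists covered DC subsets, other blood and stromal cell types, signalling and stress responses, cell cycle, metabolism and midkine with its receptors. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the 30 lists. The lists were also tested with an estimated correlation and with limma's fry, which does not compare a list with other genes. Where another setting or fewer libraries were used, list calls are at the preset correlation unless stated. For members of a list, a second adjustment was made over the list alone. Named genes were to be the 12 with the largest change in each direction among genes past the threshold, with a mean of at least 20 and no overlap between the groups. Where fewer than 5 passed in a direction, the rule took instead the 10 genes of that direction with the smallest unadjusted p that met the other conditions. Gm and Rik models were skipped. In each list, up to 4 members with the smallest p could be named. Other list members, and the genes named for the composition of the libraries, were chosen after their values were seen.

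Whole reads were also tested with edgeR 4.0.16 (quasi-likelihood, TMM) and with DESeq2 1.42.0, which gave no adjusted p to 3894 of 15443 genes. Further settings changed the pseudocount, the filter on low values, the scaling between libraries, the moderation of variances and the libraries used. After the data were seen, 4 more were added: edgeR leaving out midkine 5, limma with array weights, protein-coding genes only, and 6 further gene lists.

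The tests were tried on simulated counts for the same genes and library sizes, with 100 genes changed by each of 2 fold sizes. For 3 midkine against 3 control libraries, limma recovered 42% of genes changed by 1 on the log2 scale and 94% of those changed by 2, with 6 false calls. For 2 midkine libraries (without midkine 5) against 3, it recovered 90% and 99%, with 4 false calls. Figures were drawn with matplotlib 3.10.9.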

Results

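The transcriptome of FLT3LG-treated mouse bone marrow cells was measured with and without midkine. FLT3LG is the cytokine that drives the growth of dendritic cells (DCs) from bone marrow progenitors. Midkine is a secreted growth factor that binds heparan sulfate chains and several cell surface receptors, and was added as the human protein at 10 ng/ml for 3 days. The comparison addressed how midkine affects cells grown in this way. There were 3 control and 3 midkine libraries, with 5985684, 6117557 and 6415043 reads in control replicates 1, 2 and 4 and 6401006, 6042165 and 7233960 in midkine replicates 3, 4 and 5. Midkine 5 stood apart from the other 5 libraries on the first principal component, which held 57.1% of the variance (score 86.0, against −28.2 to 1.94). Its log2 values had Pearson correlations across genes of 0.921 to 0.941 with the other libraries, which had 0.966 to 0.985 among themselves. Mitochondrial ribosomal RNA took 0.377% of its reads (Wilson 95% interval 0.372 to 0.381%), against 4.12 and 4.69% in midkine 3 and 4 and 4.91 to 6.16% in the controls.

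Transcripts of a list of genes shared by conventional DCs were less abundant in the cultures with midkine, while the lists of DC subsets did not pass. The genes shared by conventional DCs fell as a list, with a median log2 fold change of −0.71 over 12 measured members (camera, adjusted p = 8.25e-05; adjusted p = 0.215 with an estimated correlation). The list median relative to the control mean was −0.45, −0.72 and −0.85 in midkine 3, 4 and 5. Kmo, an enzyme of tryptophan breakdown, had 677 ± 66.2 normalized counts in control and 309 ± 34.9 in midkine libraries (mean ± SD, n = 3 per group here and below). Zbtb46, a transcription factor of the conventional DC lineage, had 153 ± 16.4 and 77.3 ± 10.7. Flt3, the receptor for the cytokine in the medium, had 251 ± 7.73 and 155 ± 7.97. No member passed the limma threshold over all genes tested, and 8 were lower and 0 higher when adjusted over the list alone.

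For the subsets of DCs the lists did not pass. Genes of type 1 conventional DCs (cDC1) had a median of −0.14 over 15 members (camera, adjusted p = 0.0780; 0.643 with an estimated correlation). Adjusted over the list alone, 4 of them were lower and 0 higher: Xcr1, Snx22, Clec9a and Tlr3. Snx22 was low in counts, with 16.2 ± 0.710 in control and 2.46 ± 2.76 in midkine libraries. The list went both ways: Id2 (log2 fold change 0.46), Cd24a (0.36) and Cd36 (0.30) rose but overlapped between the groups. Without midkine 5, limma over all genes tested called 5 members lower and 3 higher, the latter being Id2, Cd24a and Cd36. Xcr1, a chemokine receptor of cDC1, had 67.8 ± 18.5 normalized counts in control and 18.1 ± 7.98 in midkine libraries, and Clec9a, a receptor for dead cells, had 37.1 ± 6.94 and 16.7 ± 3.72. The cDC1 list median was −0.62 in midkine 5, against −0.15 and −0.08 in midkine 3 and 4. The cDC1 list passed in 6 of 20 alternatives, among them edgeR (adjusted p = 0.0215), DESeq2 (0.0329), without control 2 (0.0380) and without midkine 4 (0.0268). Its adjusted p ranged from 0.0215 to 0.643 and was 0.286 without midkine 5. Type 2 conventional DC (cDC2) genes had a median of −0.07 over 13 members (adjusted p = 0.484). Adjusted over the list alone, Sirpa was higher (2082 ± 225 and 6110 ± 3421) and 5 members were lower, namely Mgl2, Klf4, Cd7, Tmem176b and Tmem176a. Klf4, a transcription factor, had 830 ± 77.7 in control and 517 ± 88.2 in midkine libraries. The cDC2 list median was 0.39 in midkine 5 and −0.25 and −0.07 in midkine 3 and 4. Plasmacytoid DC genes had a median of −0.16 over 12 members (adjusted p = 0.363). The median of the plasmacytoid DC list was −0.26 without control 4, −0.086 without control 2 and −0.10 without midkine 4. Adjusted over the list alone, Runx2 and Siglech were lower and Mzb1 was higher. Antigen presentation on MHC class II had a median of −0.14 over 11 genes (adjusted p = 0.830), MHC class I 0.01 over 13 (0.741) and DC maturation 0.12 over 14 (0.622). Of these 3 lists, only H2-D1 passed over its list alone, with 4134 ± 116 in control and 6389 ± 791 in midkine libraries.

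The lists of monocyte and macrophage genes, neutrophil genes and genes of suppressive myeloid cells rose. The monocyte and macrophage list had a median log2 fold change of 0.63 over 17 members (camera, adjusted p = 0.00137; adjusted p = 0.215 with an estimated correlation). Adjusted over the list alone, 8 members were higher and 2 lower. C1qc, a complement component made by macrophages, had 953 ± 57.8 normalized counts in control and 1940 ± 347 in midkine libraries. Mertk, a receptor for the uptake of dying cells, had 844 ± 187 and 1666 ± 80.0. The 2 lower members were chemokine receptors: Cx3cr1, with 1791 ± 165 and 1102 ± 81.7, and Ccr2, with a log2 fold change of −0.38. Neutrophil genes had a median of 0.36 over 17 members (adjusted p = 0.000299; 0.215 with an estimated correlation). The 5 that were higher when adjusted over the list alone were Camp, Mmp9, S100a9, Retnlg and Ctsg, and 0 were lower. Camp, an antimicrobial peptide of neutrophil granules, had 1964 ± 159 in control and 5008 ± 1330 in midkine libraries. S100a8 and S100a9, the calprotectin genes, together took 1.71 ± 0.101% of reads in control and 2.32 ± 0.0696% in midkine libraries. The log2 fold change of S100a9 was 0.67, but 0.085 with quantile normalization, and that of Ctsg was 0.84, but 0.55 without midkine 5. The suppressive myeloid list had a median of 0.74 over 9 members (adjusted p = 0.000273; 0.215 with an estimated correlation). Its 5 members higher over the list alone were Il1rn, Spp1, Lgals3, Trem2 and Vegfa. The other measured members, among them the cytokines Il10 and Tgfb1 as well as Chil3 and Gpnmb, did not pass over the list alone. Spp1, which encodes osteopontin, had 634 ± 37.1 and 1958 ± 614, and Lgals3, which encodes galectin-3, had 5710 ± 251 and 10836 ± 1998. Arg1, Nos2, Ido1 and Retnla, which carry the list's name most directly, had no values among the gene symbols, so the rise of the list does not cover them. All 3 lists also passed without midkine 5 at the preset correlation (largest adjusted p = 9.86e-05; adjusted p = 0.409 for each with an estimated correlation), and without midkine 4 the median of the monocyte and macrophage list was 0.42 (0.0115).

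Genes of mast cells, basophils and eosinophils had the highest list median, 1.14 over 8 members (camera, adjusted p = 0.000174; adjusted p = 0.516 with an estimated correlation and 0.0872 with fry). Over the list alone 7 of them were higher and 0 lower. Prss34, a basophil protease, had 192 ± 28.4 normalized counts in control and 463 ± 67.4 in midkine libraries, and Prg2, the major basic protein of eosinophils, had 743 ± 74.3 and 1546 ± 321. The list median was 1.30 and 1.32 in midkine 3 and 4 and 0.42 in midkine 5, where control 2 had 0.25. Genes of NF-kB signalling and inflammation had a median of 0.45 over 13 members (adjusted p = 0.00578; 0.516 with an estimated correlation and 0.104 with fry). The median of the NF-kB and inflammatory list was 0.30 without control 2 (adjusted p = 0.0227) and 0.74 with edgeR and DESeq2. Il1b, Cxcl2 and Il1a were higher when adjusted over the list alone. Cxcl2, a chemokine for neutrophils, had 56.4 ± 9.83 in control and 203 ± 86.7 in midkine libraries. B cell genes had a median of 0.48 over 11 members (adjusted p = 0.0139; 0.670 with an estimated correlation and 0.274 with fry). Only Pax5, a B cell transcription factor, passed over the list alone, with 116 ± 33.7 and 246 ± 65.1. The B cell median was 0.82 and 0.61 in midkine 3 and 4 and −0.08 in midkine 5, and the call of the B cell list was lost without control 4 (adjusted p = 0.0567), midkine 3 (0.154, median 0.30) or midkine 4 (0.0718). Of the 10 possible splits of the 6 libraries into 3 and 3, the real one did not give the smallest camera p for these lists. Splits with an unadjusted camera p as small, the real one included, numbered 2 for mast cells, basophils and eosinophils, 2 for NF-kB and 4 for B cells. The smallest other camera p was 1.04e-06, 0.000168 and 2.89e-09, against 1.16e-05, 0.00116 and 0.00325 in the real split.

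Genes of G2 and mitosis fell as a list, with a median of −0.29 over 13 members (camera, adjusted p = 0.0229; adjusted p = 0.264 with an estimated correlation). Tpx2, Top2a, Mki67 and Cenpf were lower when adjusted over the list alone, and 0 were higher. Mki67, which encodes the proliferation marker Ki-67, had 2771 ± 186 normalized counts in control and 1480 ± 481 in midkine libraries. Top2a, a topoisomerase of dividing cells, had 9147 ± 233 and 5074 ± 1251. The list went both ways in midkine 5, where Cdc20, Cdk1, Plk1, Aurka and Birc5 lay above each control (Cdk1 1371 normalized counts against 401 to 495, Plk1 1450 against 611 to 807), while Top2a, Mki67, Tpx2 and Cenpf were lowest there. The call of the G2 and mitosis list was lost without control 4 (adjusted p = 0.0567), midkine 3 (0.1101) or midkine 4 (0.0895), and its median was −0.46 without midkine 5. S phase genes had a median of −0.06 over 13 members (adjusted p = 0.363), and only Mcm7, a subunit of the replicative helicase, was lower over the list alone (2820 ± 314 and 1442 ± 347). The S phase median was −0.31 and −0.34 in midkine 3 and 4 and 0.30 in midkine 5. Without midkine 5 the S phase list passed, with a median of −0.32 (adjusted p = 0.00139; 0.477 with an estimated correlation).

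**Figure D1:**
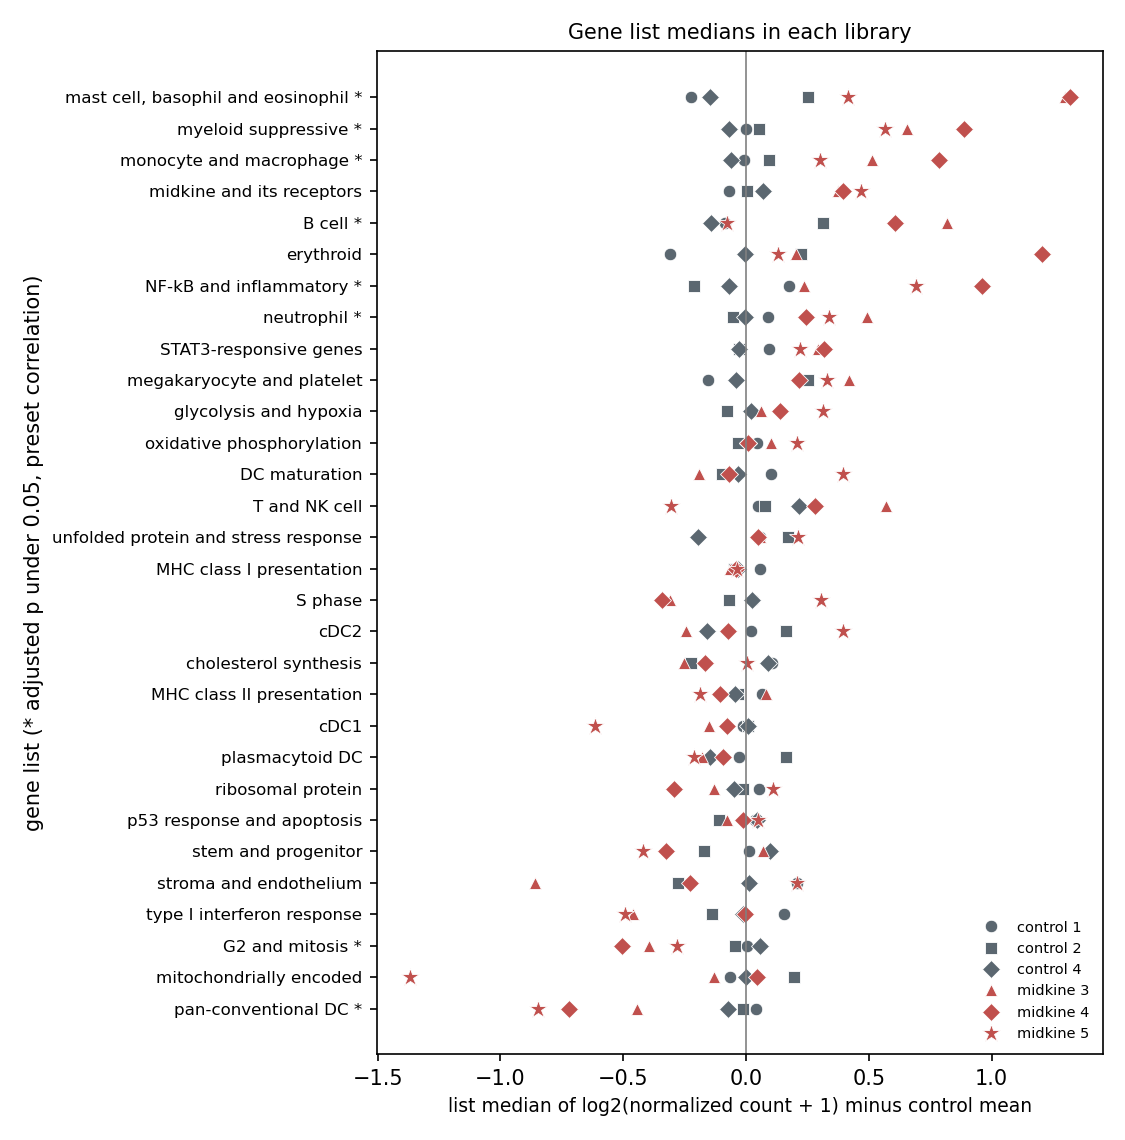
Median of each of 30 gene lists in each library (x axis, log2(normalized count + 1) minus the mean of the 3 control libraries), 1 line per list sorted by its fold change; markers stand for libraries and asterisks for lists with a camera adjusted p under 0.05 at the preset correlation. The pan-conventional DC list lies at −0.45 to −0.85 in the midkine libraries, and the mitochondrially encoded list at −1.37 in midkine 5.

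Midkine and its receptors had a median of 0.49 over 10 measured members (camera, adjusted p = 0.0731; 0.375 with an estimated correlation). The midkine and its receptors list passed in 5 of 20 alternatives, among them without midkine 5 (adjusted p = 0.00424, median 0.36; adjusted p = 0.409 with an estimated correlation), without control 2 (0.0380), with edgeR (0.0241) and with DESeq2 (0.0170). Lrp1, Cd44, Sdc3 and Mdk were higher when adjusted over the list alone. Mouse Mdk itself had 22.7 ± 8.51 normalized counts in control and 52.9 ± 15.2 in midkine libraries, and the added protein brings no RNA. The receptor Lrp1 had 720 ± 170 and 1295 ± 205. The STAT3-responsive genes list had a median of 0.35 over 15 members (adjusted p = 0.155), and 0.21 without midkine 4. Over the list alone Junb, Cebpb, Pim1, Mcl1 and Cebpd were higher and Myc was lower. Cebpb, a transcription factor of myeloid cells, had 413 ± 45.5 and 753 ± 145, and Myc had 89.6 ± 18.7 and 49.6 ± 6.04. The type I interferon response list had a median of −0.27 over 14 members (adjusted p = 0.123), and passed without control 2 (0.0380) and without midkine 4 (0.0151). With all 6 libraries the adjusted p was 0.744 with an estimated correlation. Its median was −0.18 without midkine 3 and −0.11 with array weights, and by library −0.46, −0.0029 and −0.49 in midkine 3, 4 and 5.

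The remaining lists did not pass with all 6 libraries. Among cell types, stem and progenitor genes had a median of −0.23 (adjusted p = 0.224), erythroid genes 0.48 (0.122), T and NK cell genes 0.05 (0.817), stroma and endothelium −0.25 (0.362) and megakaryocytes and platelets 0.32 (0.123). The erythroid list (without control 2, adjusted p = 0.0380) and the megakaryocyte list (0.0380) passed only without that library among the leave-one-out fits. Leaving out 1 library at a time, the median of the stroma and endothelium list ranged from −0.70 without midkine 5 to 0.21 without midkine 3, and it was −0.44 without control 2. That of the stem and progenitor list ranged from −0.37 without midkine 3 to −0.076 without midkine 5, and that of the T and NK cell list from −0.18 without midkine 3 to 0.44 without midkine 5. The erythroid list had 0.16 without midkine 4 and 0.30 without control 1, and the megakaryocyte and platelet list 0.19 without midkine 3. Over 19 alternatives of all kinds, the erythroid median ranged from 0.16 to 0.97. Over their lists alone, Hbb-bs was higher and the collagen gene Col1a2 and Sparc were lower. Glycolysis and hypoxia had a median of 0.26 (adjusted p = 0.332), oxidative phosphorylation 0.15 (0.269), cholesterol synthesis −0.11 (0.226), the unfolded protein and stress response 0.01 (0.7995) and ribosomal proteins −0.16 (0.226). Eno1 was lower over the glycolysis list alone. The cholesterol synthesis list passed without control 2 (0.0380) and the ribosomal protein list without midkine 5 (0.00424; adjusted p = 0.556 with an estimated correlation). One library moved the metabolic medians: without midkine 5 the glycolysis and hypoxia list had 0.061, the oxidative phosphorylation list 0.042 and the cholesterol synthesis list −0.24, which had −0.013 without midkine 3. Without midkine 4 the ribosomal protein list had −0.041. The p53 response list had a median of −0.16 and a mean of 0.05, with a test in the direction of lower (adjusted p = 0.830). Mitochondrially encoded genes had a median of −0.65 over 11 members (adjusted p = 0.122). It was −1.37 in midkine 5 and −0.13 and 0.05 in midkine 3 and 4, and the list passed without midkine 4 (0.0115). No member of any of the 30 lists passed the limma threshold over all genes tested. In all, 8 of 30 lists passed with camera at the preset correlation (14 without control 2), 5 passed with fry and 0 passed with an estimated correlation, where the smallest adjusted p was 0.215.

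Of single genes, 0 passed the limma threshold with all 6 libraries (smallest adjusted p = 0.0523 of 13543 genes), where 2663 had an unadjusted p under 0.05, 1404 of them higher and 1259 lower with midkine. edgeR on the recovered reads called 10 genes (6 higher, 4 lower) and DESeq2 called 684 (459 higher, 225 lower). Without midkine 5, limma called 2497 genes, 1343 higher and 1154 lower, of which edgeR on the same libraries called 2414. Of the 2497, 1970 (78.9%) had the same direction in midkine 5 against the control mean, which uses the same controls. With all 6 libraries the groups did not overlap for 1797 of them (72.0%). The 3 midkine values lay outside the range of the 3 control values for 4173 genes, or 30.8% (2100 higher, 2073 lower). Averaged over all splits of the libraries into 3 and 3, the expected share is 10%. Genes are not independent and the share in the other splits was not tested, so these values cannot tell whether 30.8% exceeds chance.

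The genes with the smallest p in each direction are given as values, since none passed the limma threshold with all 6 libraries. Dusp1, a phosphatase that switches off MAP kinases, had 125 ± 25.2 normalized counts in control and 545 ± 129 in midkine libraries (log2 fold change 2.10 ± 0.231 SE, adjusted p = 0.0523). Its gene lies on chromosome 17, 26505590 to 26562128 on the minus strand of GRCm38. Il1rn, the IL-1 receptor antagonist (chromosome 2, 24336853 to 24351494, plus strand), had 279 ± 36.3 and 706 ± 57.4 (log2 fold change 1.34 ± 0.159 SE, adjusted p = 0.0523). Il1b, the cytokine IL-1β, had 223 ± 9.18 and 456 ± 29.7. Clec7a, which encodes the β-glucan receptor dectin-1 and is classed as a polymorphic pseudogene in the annotation, had 1356 ± 151 and 3431 ± 726. Other higher genes were Rcan1 (50.6 and 164), an inhibitor of calcineurin, Jchain (130 and 352), the joining chain of secreted antibodies, the related membrane proteins Emp1 (235 and 773) and Pmp22 (195 and 554), Gpd1 (7.75 and 41.3), a glycerol-3-phosphate dehydrogenase, and Ccl24 (17.2 and 64.4), an eosinophil chemokine.

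Among genes lower with midkine, Tagln, an actin-binding protein of smooth muscle and mesenchymal cells, had 113 ± 23.0 normalized counts in control and 16.0 ± 3.68 in midkine libraries (log2 fold change −2.75 ± 0.261 SE, adjusted p = 0.0523). Its gene lies on chromosome 9, 45929619 to 45936058 on the minus strand. Kif5a, a kinesin, had 49.4 and 8.45, Gem, a small GTPase, had 105 and 34.7, and Lifr, the receptor of leukaemia inhibitory factor, had 256 and 102. Cd300c had 92.7 and 32.0, Luc7l3 2705 and 1414, Hist1h2bk, a histone gene, 62.5 and 18.0, Acrbp 78.2 and 32.7, and Sept3, a septin also on the pan-conventional DC list, 133 and 60.5. Kmo was the tenth. For all 20 genes the 3 midkine values lay outside the range of the 3 control values, the limma adjusted p lay between 0.0523 and 0.0757, and limma without midkine 5 called each of them. With all 6 libraries, edgeR called Dusp1, Rcan1, Jchain, Il1rn, Emp1, Gpd1 and Tagln (adjusted p = 0.0462 each). DESeq2 with all 6 libraries called all 20 (largest adjusted p = 0.00164, for Acrbp). The genes were selected on no overlap and a small p in the same libraries, so these calls are not independent evidence. Exons on the opposite strand overlap those of Dusp1 (Ergic1), Gpd1 (Gm16537), Il1b (Il1bos), Tagln (Pcsk7 and Gm48529) and Acrbp (4930557K07Rik), and Acrbp also overlaps Gm44597 on its own strand, so reads of these pairs may be mixed.

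**Figure D2:**
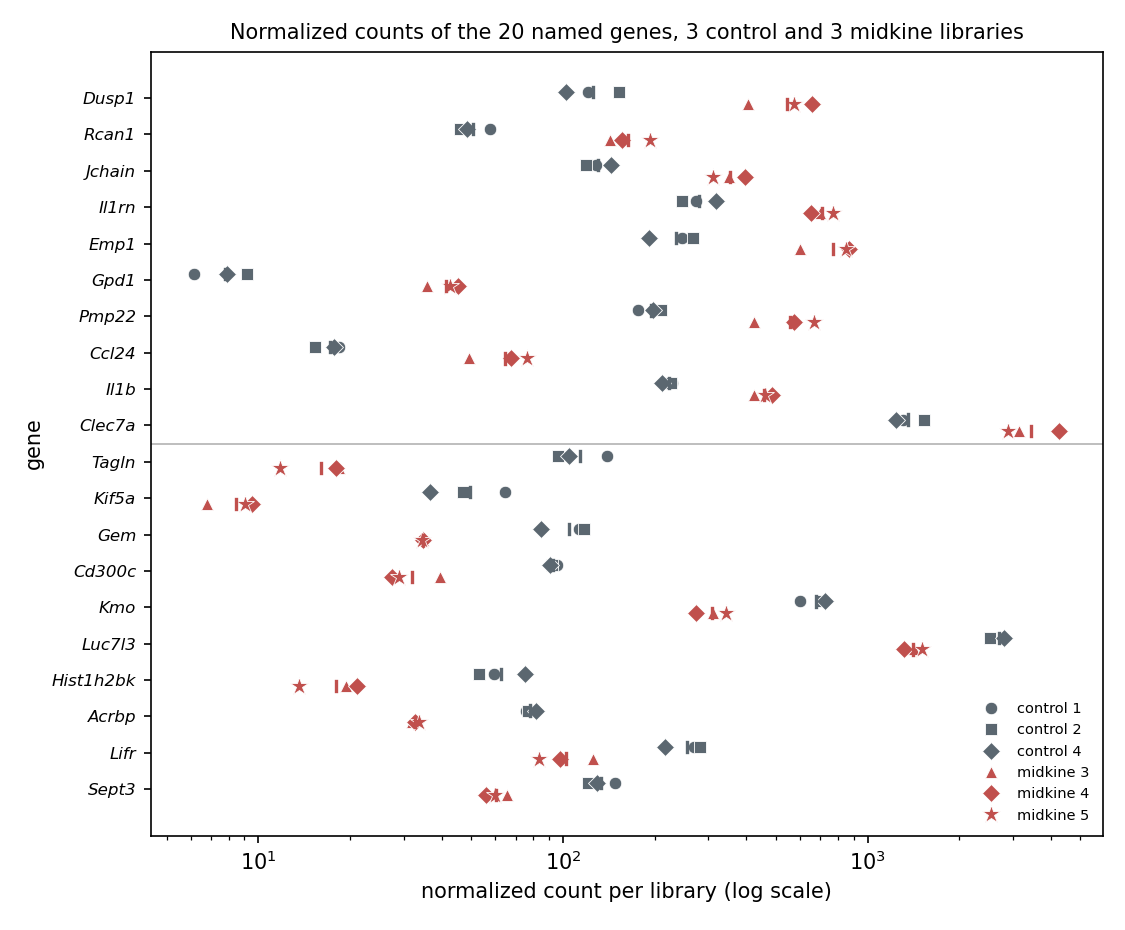
Normalized counts (x axis, log scale) of the 20 named genes in the 3 control libraries (grey) and the 3 midkine libraries (red), with vertical ticks at the group means; genes above the line were higher and those below it lower with midkine. The groups do not overlap for any of these genes, which were selected on that condition, so midkine 5 (star) lies on the side of the other midkine libraries by selection.

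The composition of the libraries also differed. Gm42418, a non-coding gene model that lies within the 45S ribosomal RNA precursor gene, took 6.67 ± 1.38% of reads in control and 3.19 ± 1.55% in midkine libraries, with 1.49% in midkine 5 (Wilson 95% interval 1.48 to 1.50%). Mitochondrial ribosomal RNA took 5.58 ± 0.633% and 3.06 ± 2.34%. The nuclear RNA Malat1 took 0.344 ± 0.00978% and 0.207 ± 0.0971%, with 0.0957% in midkine 5 (Wilson 95% interval 0.0934 to 0.0979%). The 3 midkine libraries lay below the 3 control libraries for each of these 3 classes, for which an exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1. The nuclear RNA Neat1 went the other way in midkine 5, with 0.0669% (Wilson 95% interval 0.0650 to 0.0688%), against 0.0214 and 0.0193% in midkine 3 and 4 and 0.0337 to 0.0425% in the controls.

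**Figure D3:**
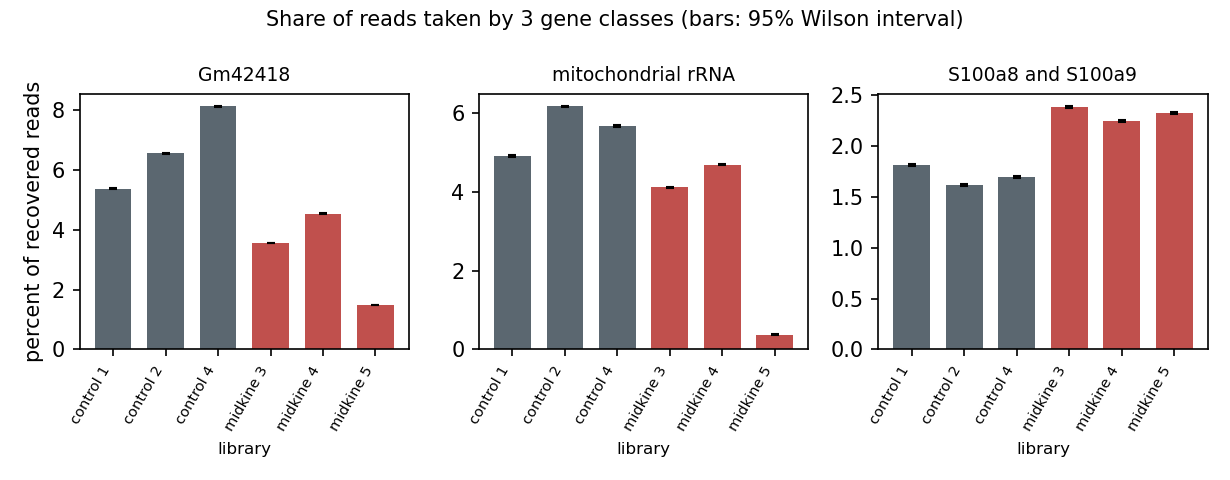
Percent of recovered reads (y axis, from 0) taken by Gm42418, by mitochondrial ribosomal RNA and by S100a8 with S100a9 in each library; grey bars are control, red bars midkine, and error bars are Wilson 95% intervals for counting error. Mitochondrial ribosomal RNA took 0.377% in midkine 5 and 4.12% or more in every other library.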

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

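Array weights, protein-coding genes only and edgeR leaving out midkine 5 were chosen after the data were seen. The list of genes shared by conventional DCs had a lower median in all 20 alternatives (−0.81 to −0.60) and lost its call in 1 of them, the estimated correlation (−0.71, adjusted p = 0.215). The plasmacytoid DC and cDC2 lists passed in none of 20. The test of the cDC2 list had the direction of lower in each, but its median lay between −0.32 and 0.21. Where results changed, the cause was not tested. Simulated changes were called with 3 against 3 libraries. The simulated counts were drawn independently with 1 dispersion per gene, and no simulated library stood apart as midkine 5 did. The simulation therefore cannot tell what set the low count of genes. No paired analysis was possible because the groups share only replicate number 4. Depth limits statements on low genes to counts above the floor of 3 reads per library.

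Against 0 genes (0 higher, 0 lower, 0 list members) with limma and all 6 libraries, the counts were 10 genes (6 higher, 4 lower) and 1 list member with a pseudocount of 5. They were 9 (6 and 3) and 1 with no filter, 7 (5 and 2) and 1 with TMM scaling, and 12 (7 and 5) and 1 with total scaling. With quantile normalization they were 16 (8 and 8) and 2, with edgeR on recovered reads 10 (6 and 4) and 1, and with DESeq2 on recovered reads 684 (459 and 225) and 59. With array weights, where midkine 5 had a weight of 0.0967, they were 5076 (2589 and 2487) and 210, and with edgeR leaving out midkine 5 they were 2508 (1428 and 1080) and 153. Leaving out 1 library at a time gave 0 to 2497 genes, 0 to 1343 higher, 0 to 1154 lower and 0 to 150 list members, above 0 only without midkine 5. The 8 lists called became 6 to 14 in this way, 0 with an estimated correlation and 5 with fry.

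The median of the cDC1 list, which did not pass (−0.14), was past the threshold with quantile normalization (−0.153, adjusted p = 0.0363), edgeR on recovered reads (−0.141, 0.0215), DESeq2 on recovered reads (−0.135, 0.0329) and protein-coding genes only (−0.143, 0.0411). Leaving out 1 library at a time, it ranged from −0.368 to −0.0725.

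Lists and genes that turned in direction were past the threshold in neither case. With quantile normalization the MHC class I list had −0.122. With array weights the DC maturation list had −0.127, the unfolded protein list 0.0322, the p53 list −0.0137, the mitochondrially encoded list 0.0257 and mt-Co1 0.0115. With DESeq2 the p53 list had −0.114. Leaving out 1 library at a time, the MHC class II list ranged from −0.152 to 0.0288, DC maturation from −0.125 to 0.235, T and NK cells from −0.184 to 0.437, the unfolded protein and stress response from −0.0699 to 0.104, the p53 response and apoptosis list from −0.175 to −0.0318 and Nkg7 from −0.0131 to 0.437. These turned without midkine 5 (MHC class II, DC maturation, unfolded protein), midkine 3 (T and NK cells, p53, Nkg7), control 1 (T and NK cells) and control 4 (unfolded protein). For lists the direction is that of the test, so a median can keep its sign.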

Other observations

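Chosen after the results were seen were the 6 gene lists below, the tests of a stronger response, of a GC trend alone, of RNAs without a poly(A) tail, of midkine 5 alone for unassigned gene models, of a lower share of dendritic cells, and the count of splits for limma. Lysosomal genes rose as a list, with a median log2 fold change of 0.59 over 26 members (camera, adjusted p = 7.32e-09 over the 6 lists; adjusted p = 0.0488 with an estimated correlation), and 18 of them were higher in 3 of 3 midkine libraries. The cathepsin Ctsl, a lysosomal protease, had 1085 ± 212 normalized counts in control and 2656 ± 537 in midkine libraries (mean ± SD, n = 3 per group), Ctsb had 8953 ± 1725 and 16260 ± 3061, and Ctsd had 25587 ± 4009 and 43512 ± 4978. The log2 fold change of Ctsd was 0.77, but 0.27 with quantile normalization. Genes of lipid-associated macrophages rose as a list, with a median of 0.79 over 15 members (adjusted p = 8.62e-10; adjusted p = 0.0691 with an estimated correlation), and 11 of them were higher in 3 of 3 midkine libraries. The others overlapped between the groups: Gpnmb (log2 fold change 0.58), Apoe (0.63), Plin2 (0.60) and Cd36 (0.30), which in midkine 5 was lower than in each control. Fabp4 and Fabp5, which bind fatty acids, had 397 ± 154 and 1252 ± 118, and 6719 ± 1289 and 14336 ± 1702. Osteoclast genes rose as a list, with a median of 0.72 over 11 members (adjusted p = 0.000205; adjusted p = 0.0488 with an estimated correlation). Only 6 of them were higher in 3 of 3 midkine libraries. Members that overlapped between the groups included Nfatc1 and Itgb3 (log2 fold change −0.15 each), Dcstamp (0.32) and Car2 (0.42). Acp5, the tartrate-resistant phosphatase of osteoclasts, had 112 ± 6.55 and 350 ± 120, and Ctsk, their collagen-degrading protease, had 9.42 ± 3.78 and 29.8 ± 0.955.

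Eosinophil genes rose as a list, with a median of 1.19 over 10 members (adjusted p = 2.66e-07; adjusted p = 0.0488 with an estimated correlation). The ribonuclease Ear2 had 20.9 ± 1.58 normalized counts in control and 60.8 ± 6.92 in midkine libraries. Of the members, 6 were higher in 3 of 3 midkine libraries, among them the chemokine Ccl24. The others overlapped between the groups: Il5ra (log2 fold change −0.47), Siglecf (0.41), Epx (1.24) and Ear6 (1.37). Immediate early genes rose as a list, with a median of 0.41 over 18 members (adjusted p = 3.83e-06; adjusted p = 0.0560 with an estimated correlation), and 0.67 without midkine 5 (adjusted p = 8.19e-08). Of these members 10 were higher and 0 lower in 3 of 3 midkine libraries. Members that overlapped between the groups included Fos (log2 fold change 0.35), Egr1 (0.41), Egr3 (−0.06), Jund (−0.13) and Atf3 (−0.02). In midkine 5, Fos, Jund and Atf3 were lower than in each control. The nuclear receptor Nr4a1 had 16.9 ± 6.19 and 55.6 ± 8.65, and the transcription factor Egr2 had 26.7 ± 8.96 and 73.6 ± 33.4. Actin and mesenchymal genes fell as a list, with a median of −0.24 over 13 members (adjusted p = 0.0226; adjusted p = 0.156 with an estimated correlation) and −0.66 without midkine 5 (adjusted p = 0.0365), but went both ways. Of its members 4 were lower and 2 higher in 3 of 3 midkine libraries, the higher ones being Fn1, which encodes fibronectin (323 ± 50.7 and 550 ± 44.4), and Vim (4451 ± 208 and 5035 ± 198), whose log2 fold change of 0.18 was 0.042 with quantile normalization. These lists were drawn up after genes such as Tagln, Ccl24 and Dusp1 had been seen among those with the smallest p, so their p-values are not independent evidence. Genes also named in the report or on a list fixed before numbered 6 in the lipid-associated macrophage list, 4 in the immediate early list, 3 in the eosinophil list, 2 in the actin list, 1 in the osteoclast list and 0 in the lysosome list. The lists also share members: Ctsb, Ctsd and Lipa are in both the lysosome and the lipid-associated macrophage list, and Atp6v0d2 is in both the lysosome and the osteoclast list.

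The tables argue against midkine 5 alone as the source of the lower conventional DC genes and higher myeloid genes, since without it the conventional DC, suppressive myeloid, monocyte and macrophage, and neutrophil lists kept their direction, with a largest adjusted p of 0.000121 at the preset correlation (adjusted p = 0.409 for each with an estimated correlation). Under TMM, total and quantile scaling, the largest adjusted p of the conventional DC and suppressive myeloid lists was 0.00141 at the preset correlation (adjusted p = 0.215 for both with an estimated correlation, as deposited). A lower share of DCs alone would raise the markers of all other lineages alike. Their medians lay 1.36 apart, from −0.23 for stem and progenitor genes to 1.14 for mast cells, basophils and eosinophils. The range of the 6 list medians was 0.83 to 1.64 in the midkine libraries and 0.36 to 0.73 in the controls, each control set against the other controls (permutation p = 1e-05 over members of all 6 lists, the smallest the draws can give, with members taken as independent). Members are not independent: the mast cell, basophil and eosinophil list had an estimated correlation of 0.71. Its median in midkine 5 was 0.42, where control 2 had 0.25. The medians thus differed, but the test cannot decide whether a lower share of DCs alone would suffice. A shift in the cells that grew, or a change within them, may underlie the pattern and cannot be separated in these bulk libraries.

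The 10 splits of 6 libraries cannot give a share under 0.1: the real split called 8 lists and 3 of 10 splits called as many, the highest other 10. The real split gave the smallest camera p for the conventional DC, monocyte and macrophage, neutrophil, suppressive myeloid, and G2 and mitosis lists. It did not for the mast cell, basophil and eosinophil, NF-kB and B cell lists. With edgeR it called 10 genes, as 1 of 10 splits did, the highest other 0, and with limma 0, as 10 of 10 did, the highest other 0.

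Midkine 5 stood apart from midkine 3 and 4, and a stronger response in that culture would make its extra deviation follow the effect in other libraries, but Pearson's r across genes was 0.107 with midkine 4 and −0.089 with midkine 3 (mean 0.0088), which argues against it as the whole cause. The effect in midkine 5 had an r of 0.383 with that in midkine 3 and 4 where control 1 was held apart (0.274 and 0.342 for controls 2 and 4), and midkine 3 had 0.494 with midkine 4 where control 1 was held apart. Removing a trend with the GC content of the 3′ end left an SD across genes of 0.712, from 0.745 before, against 0.280 between midkine 3 and 4, which argues against that trend as the whole cause, while Spearman's rho with GC of 0.299 across genes (−0.0249 to 0.136 between other libraries of a group) leaves a part open. Fewer reads from RNAs without a poly(A) tail may be part of the difference: over 96 genes of small nuclear and nucleolar RNA, mitochondrial ribosomal RNA and histones the median deviation was −0.91, where 1000 draws matched on expression gave −0.40 to 0.29. The loss was not confined to this set. Mitochondrial mRNA, which is outside it, took 0.195% of reads in midkine 5, against 0.491 and 0.524% in midkine 3 and 4. Genes are not independent replicates in these tests, and a difference in library preparation or in that culture was not tested.

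Gene models of the TEC class, a provisional class of the annotation, had a median log2 fold change of −0.52 over 527 models. Against the control mean, their median was −0.17, −0.35 and −0.86 in midkine 3, 4 and 5. It was −0.065, 0.12 and −0.0078 in control 1, 2 and 4, so midkine 3 lay close to control 1. The models are not independent replicates. Midkine 5 alone did not account for the lower TEC median, since without that library the TEC median minus that of protein-coding genes was −0.30. Nor did low expression, since their median minus the mean of protein-coding draws matched on expression was −0.27 (medians of the draws −0.099 to 0.092). Fewer reads from unspliced transcripts may contribute and stay open: the median of 418 models within introns, relative to their host genes, minus that of 64 models outside genes was −0.077 (permutation p = 0.277; bootstrap −0.23 to 0.037).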
